A study of Mus musculus with 18 samples.

How the data were processed

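RNA abundance was measured by bulk RNA sequencing of mouse bone marrow cells that were wild type (WT), heterozygous (HET) or homozygous knockout (KO) for Fabp4, which encodes a fatty acid binding protein best known from adipocytes and macrophages. The labels describe 18 samples in 6 groups of 3. Of these, 9 were sorted from a preparation that the labels call vitro bone marrow, named the in vitro set here, and 9 were sorted from bone marrow. The labels name neither the sorted population nor the culture. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a VAHTS Universal kit. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here.

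The values used were FPKM (fragments scaled by transcript length in kilobases and by mapped fragments) that the authors deposited, per the file headers, in a table for each set. The in vitro set had 22017 genes in 9 libraries and the bone marrow set had 13195 genes in 8 libraries, with 12604 genes in both. Replicate 2 of the HET bone marrow group was not used here, so that group had n = 2. FPKM are scaled for transcript length and library size, hold no raw counts, and move for every other gene when a few transcripts take a large share. The 2 tables may have been scaled separately, so groups were compared within a table. An exact 0 can be a failed estimate as well as an absence, and such genes are given as listed at 0.

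Sequencing depth was estimated from the values, since low values of genes with a single exon step by what 1 fragment is worth. The estimates were 30.7 to 36.9 M fragments in vitro and 3.96 to 35.8 M in bone marrow, and 72.4 to 84.7% of low values lay within 0.1 of a whole step. These depths are approximate and entered no test.

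Tests were run with limma 3.58.1 in R 4.3.3 (statmod 1.5.0, and data.table at version 1.17.8) on log2(FPKM + 1), with an intensity trend and robust variance moderation. Genes with FPKM of at least 1 in at least 3 libraries of a table were kept, which left 10877 in vitro and 7246 in bone marrow. All genotypes of a table shared a fit with a mean per genotype and no block, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A log2 change on this scale understates the change of genes with low values. The difference between the sets in the KO against WT change was tested in a joint limma fit over 10041 genes. Fabp4 itself was compared by an exact two-sided permutation test, which cannot give a p below 0.1 with 3 libraries against 3. The p-values measure the spread between these libraries. The design text speaks of 3 mice per genotype and set and does not say that each library came from a separate mouse or that the sets shared mice. Every in vitro library held transcripts of the X inactivation RNA gene Xist and of Y genes, so a library may mix cells of several mice. The p-values may then not measure the spread between mice.

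Gene lists (39 lists, 869 names, of which 820 matched in vitro and 674 in bone marrow) covered stem and leukemia programs, lipid and energy metabolism, stress responses, the cell cycle, blood lineages and other cell types. They were tested with camera from limma at a preset correlation between genes of 0.01, adjusted over lists within a comparison, and again with an estimated correlation and with fry. Only matched genes that passed the filter entered these tests. This left 12 of 26 macrophage genes in vitro and 8 of 25 hematopoietic stem cell genes in bone marrow. The genes named in the text followed a fixed rule. It took Fabp4 and tested members of its family. It then took the 8 largest rises and 8 largest falls among called genes whose groups did not overlap and reached a mean FPKM of 2 in either group (5 each way for KO against HET and for the difference between the sets). It added up to 4 members with the smallest p of each called list and of the lists of leukemia stem cells, hematopoietic stem cells, fatty acid oxidation and PPARG targets. Predicted genes, pseudogenes and antigen receptor segments were counted and not named, and some genes that met the rule are not reported here. The design, the lists, this rule and the first set of alternatives were chosen before the data were examined. Gene positions are those of GRCm38.p6, the assembly that mm10 holds.

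The alternatives were a pseudocount of 0.1, no filter beyond a value above 0 in 3 libraries, a filter at FPKM of 5, quantile normalization, median-ratio size factors and rescaling to TPM. Others were only the compared groups in the fit, the replicate number as a block, array weights, fits of each set alone, and leaving out each library in turn. Leaving out genes of chromosomes X and Y, keeping genes above 0 in every library of the bone marrow table, and fitting each set alone with a t distribution were added after the data were seen. So were the alternatives for changes shared by HET and KO. The limma fits, camera and the fits for the difference between the sets were tested on simulated data in 5 runs each. The fits had 200 changed genes per run, each gene varied independently, and the other steps were not tested this way. For KO against WT, the in vitro design recovered 65.2% of genes changed by 0.5 log2, 99.2% at 1, 98.4% at 2 and 100% at 4, and 5.82% of calls were false. The bone marrow design recovered 0% at 0.5 and 1, 2.4% at 2 and 8.4% at 4, and 6.9% of calls were false. The joint fit for the difference between the sets recovered 45.6% at 4 log2 with a mean of 34.2 false calls per run. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.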

Results

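Transcript abundance in FPKM was compared between Fabp4 wild-type, heterozygous and homozygous knockout bone marrow cells in an in vitro set (n = 3 libraries per genotype) and in a sorted bone marrow set (n = 3 WT, 2 HET and 3 KO libraries). The series title asks about Fabp4 in the maintenance of leukemia stem cells and in hematopoietic stem cells. The estimated depth in vitro was 36.9, 35.5 and 31.5 M fragments for the WT libraries, 34.8, 34.2 and 30.7 M for HET and 33.6, 32.1 and 34.0 M for KO. In bone marrow it was 21.8, 25.8 and 31.6 M for WT, 3.96 and 11.6 M for HET replicates 1 and 3, and 16.4, 34.0 and 35.8 M for KO. The in vitro libraries listed 16779 to 18029 genes above 0 and correlated with each other at a Spearman coefficient of 0.962 to 0.970 across genes. The bone marrow libraries listed 8194 to 8526 genes above 0 in WT, 3633 and 5209 in HET and 6560 to 8519 in KO, and correlated at 0.427 to 0.621. None of the 36 in vitro or 28 bone marrow pairs of libraries held identical values (0 pairs).

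Fabp4, the targeted gene on chromosome 3 (10204342 to 10208616), was close to 0 in vitro in every genotype. It was listed at 0, 0.0326 and 0.330 FPKM in the WT libraries, at 0, 0.0676 and 0 in HET and at 0 in all 3 KO libraries. The KO minus WT difference of -0.121 FPKM lay within the spread between libraries (exact two-sided permutation p = 0.4, with 0.1 the smallest possible), as did HET against WT (exact permutation p = 0.7). These values are too low to check the genotype labels. Fabp4 was not analysed here in the bone marrow set. Fabp5, the epidermal fatty acid binding protein gene on the same chromosome (10012585 to 10016610), was the other tested member of the family. Fabp5 fell in vitro from 89.6 ± 13.0 FPKM in WT to 47.1 ± 2.58 in KO (SD, n = 3), a log2 change of -0.90 ± 0.10 (SE, limma adjusted p = 0.00098), with all 3 KO libraries below all 3 WT libraries. In HET cells it was 73.7 ± 3.62 FPKM, which was not past the threshold against WT (adjusted p = 0.137), and KO lay below HET (log2 change -0.64, adjusted p = 0.0059). In bone marrow Fabp5 was listed at 0, 0.0406 and 37.2 FPKM in WT, at 0 in both HET libraries and at 0, 7.41 and 26.4 in KO (adjusted p = 0.999 for KO against WT).

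In vitro, KO cells had lower transcripts of the hypoxia response and of glycolysis than WT cells. Of 24 hypoxia genes 15 fell and 0 rose (18 fell and 1 rose when adjusted over the list alone), with a median log2 change of -0.68. The glucose transporters Slc2a1 (79.6 ± 10.9 FPKM in WT and 32.0 ± 8.73 in KO, adjusted p = 0.00346) and Slc2a3 (111 ± 8.73 and 46.9 ± 2.11, adjusted p = 0.00103) fell by 1.31 and 1.22 on the log2 scale. The lactate exporter gene Slc16a3 fell by 1.11 (adjusted p = 0.00172) and lactate dehydrogenase A (Ldha) by 0.44 (534 ± 10.2 and 393 ± 25.6 FPKM, adjusted p = 0.00602). The oxygen-sensing prolyl hydroxylase gene Egln1 fell by 1.17 and the hypoxia-inducible mitochondrial gene Higd1a by 0.62 (both adjusted p = 0.00262). Among the 8 largest falls were also the hypoxia-responsive gene Ndrg1 (log2 change -1.36, 95.6 ± 14.3 and 36.5 ± 4.65 FPKM, adjusted p = 0.0104) and Ankrd37 (-1.25, 0.0497). The others were the secreted hormone genes Apln (-1.51, 0.0018) and Stc2 (-1.26, 0.00103), Smtnl2 (7.46 and 1.17 FPKM, 0.00358) and the eosinophil-associated ribonuclease gene Ear2 (-2.04, 0.0336). Of 24 glycolysis genes 11 fell and 1 rose (17 and 3 adjusted over the list alone), with a median log2 change of -0.26. Both lists were called lower by camera (adjusted p = 8.42e-16 for hypoxia and 1.17e-09 for glycolysis) and neither with an estimated correlation (adjusted p = 0.32 and 0.286 with an estimated correlation). Leaving out a library ended the calls of Ndrg1 (WT 3, KO 1 or KO 3, adjusted p up to 0.0706) and Ear2 (WT 2, WT 3, KO 1, KO 2 or KO 3, up to 0.193). That of Ankrd37 ended without any of WT 1 to 3, HET 2, HET 3, KO 1 or KO 3 (up to 0.212), and with a filter at FPKM of 5, quantile normalization, TPM or only these groups in the fit (0.0526, 0.0625, 0.0574 and 0.0691). With no filter on low values those of Ankrd37 and Ear2 ended (0.0976 and 0.0754).

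Immediate early genes, which cells induce within minutes of a stimulus and also during handling, were higher in KO than in WT cells in vitro. The AP-1 transcription factor gene Fos rose from 83.5 ± 11.1 to 390 ± 38.1 FPKM (log2 change 2.21 ± 0.12, adjusted p = 1.83e-06) and its relative Fosb by 1.97 log2 (adjusted p = 0.000134). The phosphatase gene Dusp1 rose by 1.42 (adjusted p = 0.00098) and the nuclear receptor gene Nr4a1 by 1.17 (adjusted p = 0.000813). Of 23 measured immediate early genes 9 rose and 0 fell (15 rose and 2 fell adjusted over the list alone). The median log2 change was 0.59, and camera called the list (adjusted p = 3.18e-08, and adjusted p = 0.32 with an estimated correlation). The largest rise of all belonged to Ly6k, a GPI-anchored protein gene of the Ly6 family on chromosome 15 (74796874 to 74799968). It went from 0.288 ± 0.0371 FPKM in WT to 21.0 ± 0.612 in KO (log2 change 4.09 ± 0.11, adjusted p = 2.33e-09). The calpain gene Capn11 (0.0197 and 2.63 FPKM, log2 change 1.83, adjusted p = 1.83e-06) and the peptide transporter gene Slc15a2 (0.446 and 2.79 FPKM, 1.39, 7.77e-05) also rose. So did the chemokine gene Cxcl2 (1.28, 0.0368). The call of Cxcl2 ended without WT 2, WT 3, HET 2, KO 2 or KO 3 (adjusted p up to 0.177) and with no filter on low values (0.0776). Capn11 and Slc15a2 failed the filter with any KO library left out, so only 6 refits cover each.

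**Figure D1:**
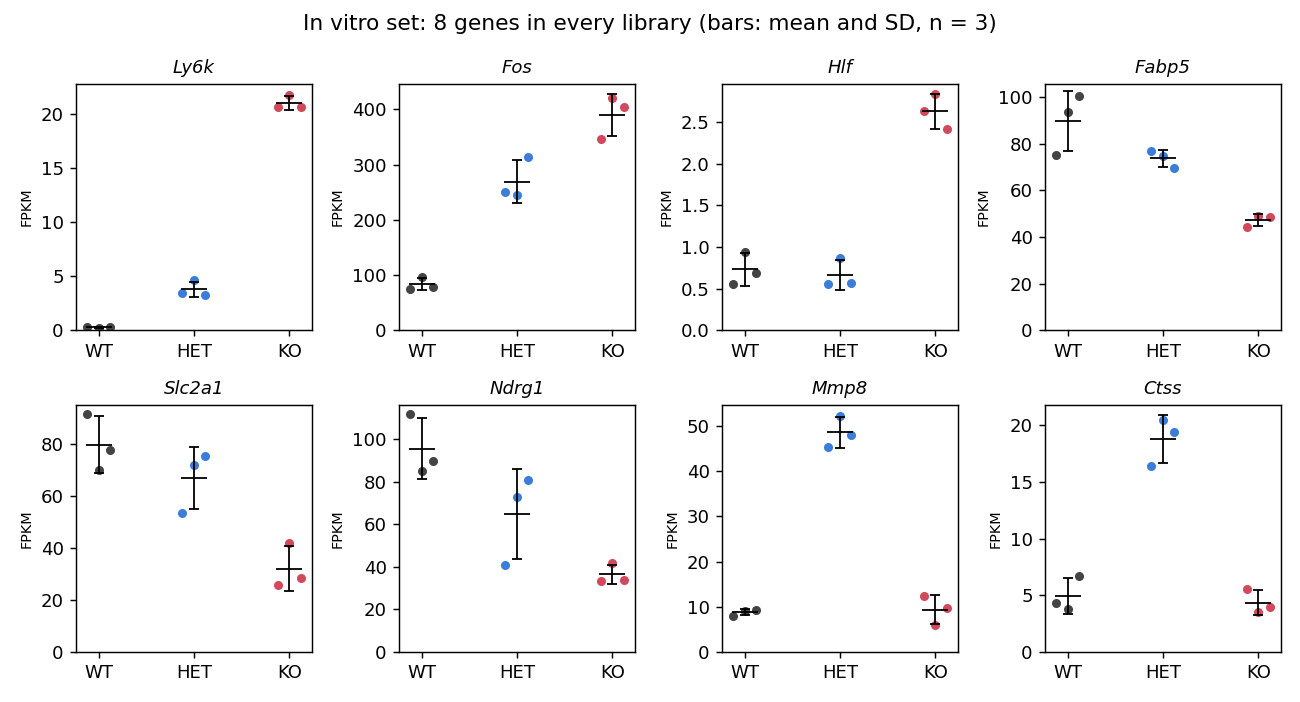
FPKM of 8 genes in each in vitro library (points), with the mean and SD of the 3 libraries per genotype (bars), for WT, HET and KO on the x axis. Ly6k reached 21.0 FPKM in KO against 0.288 in WT, Slc2a1 and Ndrg1 were lowest in KO, and Mmp8 and Ctss were highest in HET.

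The lists of the study question moved little between KO and WT cells in vitro. Of 17 hematopoietic stem cell genes 1 rose and 0 fell (5 rose adjusted over the list alone), with a median log2 change of 0.16. The gene that rose was Hlf, a transcription factor of stem and progenitor cells, from 0.731 ± 0.196 to 2.63 ± 0.211 FPKM (log2 change 1.07 ± 0.12, adjusted p = 0.00103). With any KO library left out Hlf failed the filter and was not tested, so only 6 refits cover it. Kit, the stem cell factor receptor, was at 23.3 and 30.2 FPKM (adjusted p = 0.121). The list was called by camera (adjusted p = 0.0372), not with an estimated correlation (adjusted p = 0.343 with an estimated correlation) nor without WT 1, HET 1, KO 1, KO 2 or KO 3 (0.115, 0.0622, 0.184, 0.113 and 0.223). Camera also did not call it with a pseudocount of 0.1 (0.0568), while fry called it (fry adjusted p = 0.0204). Of 27 leukemia stem cell genes 2 rose and 0 fell (2 adjusted over the list alone), and the list was not called (adjusted p = 0.0575). The genes were Pbx3, a HOX cofactor (5.27 and 9.11 FPKM, log2 change 0.69, adjusted p = 0.00288), and the receptor kinase gene Flt3 (1.39 and 2.73 FPKM, 0.64, 0.0168, up to 0.0754 without WT 2, KO 1 or KO 3). Of 24 fatty acid oxidation genes 1 fell, the lipid-sensing nuclear receptor gene Ppard (9.50 and 4.91 FPKM, log2 change -0.83, adjusted p = 0.00319), and the list was not called (adjusted p = 0.391). Of 12 PPARG targets 2 fell, Fabp5 and the cholesterol exporter gene Abcg1 (log2 change -0.65, adjusted p = 0.00768, and 0.0572 without KO 3). The median of the PPARG targets was 0.03 and their mean -0.09, the direction of camera was down, and camera did not call the list (adjusted p = 0.279). Fry called it (fry adjusted p = 0.0396).

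Markers of monocytes and macrophages were higher in KO than in WT cells in vitro, with 2 of 12 tested markers (of 26 in the list) rising and 0 falling (7 rising adjusted over the list alone). The median was 0.34 (adjusted p = 0.00275, and adjusted p = 0.233 with an estimated correlation). The monocyte chemokine receptor gene Ccr2 rose from 12.3 ± 1.22 to 26.1 ± 2.57 FPKM (log2 change 1.03, adjusted p = 0.000439). Of 29 genes of endoplasmic reticulum and amino acid stress 2 fell, the asparagine synthetase gene Asns (log2 change -0.45, adjusted p = 0.0044) and the stress-induced pseudokinase gene Trib3 (-1.14, 0.00768). The list was called lower (median -0.10, 1 rising and 7 falling adjusted over the list alone, adjusted p = 0.00243, and adjusted p = 0.32 with an estimated correlation). Of 18 fatty acid synthesis genes 2 fell, the desaturase genes Scd1 (log2 change -0.50, adjusted p = 0.0231) and Scd2 (312 and 224 FPKM, 0.0254). Both lost their call without WT 2, KO 1 or KO 3 (up to 0.102 and 0.121), with no filter on low values (0.064 and 0.0712) and after rescaling to TPM (0.0604 and 0.077). That of Scd2 also ended after quantile normalization (0.101) and with only these groups in the fit (0.0703). The list was called lower (median -0.09, 4 falling and 1 rising adjusted over the list alone, adjusted p = 0.00806, and adjusted p = 0.461 with an estimated correlation). Of 25 genes of NF-kappaB signalling 3 rose and 0 fell (5 adjusted over the list alone, median 0.20, adjusted p = 0.0347, and adjusted p = 0.581 with an estimated correlation). Among them was Junb, another AP-1 member (105 ± 21.2 and 187 ± 14.6 FPKM, log2 change 0.84, adjusted p = 0.00634). The NF-kappaB list was not called without WT 1, WT 2, HET 1 or KO 2 (0.227, 0.0575, 0.0509 and 0.116).

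By limma, 325 of 10877 genes changed between KO and WT cells in vitro, 148 up and 177 down (45.5% up), with 15 up and 23 down by at least 2-fold and 2114 at unadjusted p under 0.05. The groups did not overlap for 22.9% of tested genes, where chance gives 10%. The split was 120 up and 222 down (35.1% up) after quantile normalization and 117 up and 228 down (33.9% up) with median-ratio size factors. Rises outnumbered falls without WT 1 (206 up and 180 down, 53.4% up), without KO 2 (240 and 235) and with array weights (3476 and 1864). Camera called 18 of 39 lists, 9 higher and 9 lower, and 0 with an estimated correlation (adjusted p from 0.233 to 0.625). The Fabp family list among the 18 held 1 tested gene, Fabp5. Splits of these 6 libraries that mixed the genotypes gave up to 17 called lists. The number of called lists alone therefore does not set the genotypes apart. Fry called 9, among them hypoxia (fry adjusted p = 0.0366), glycolysis and immediate early (both 0.0128) and macrophage (0.00536). It did not call oxidative phosphorylation (0.267) or MYC targets (0.4). The 21 lists not called by camera, such as those of progenitor cells, ribosomal proteins, lipid droplets and lipid uptake, p53 targets and apoptosis, had adjusted p from 0.0575 to 0.933. The count of genes was 138 without WT 2, 197 without HET 2, 71 without KO 1 and 66 without KO 3. It was 152 with no filter on low values, 176 with only these groups in the fit and 5340 with array weights, whose estimation did not converge.

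In HET cells in vitro, genes of macrophages and of neutrophil granules were higher than in WT. Transcripts of Y genes were also highest in HET, so donor sex cannot be told apart from genotype for these rises. Of 12 macrophage markers 7 rose and 0 fell (9 adjusted over the list alone), with a median log2 change of 1.03. The lysosomal protease gene Ctss rose from 4.93 ± 1.56 to 18.8 ± 2.10 FPKM (log2 change 1.76 ± 0.18, adjusted p = 0.000257) and Ccr2 from 12.3 ± 1.22 to 34.0 ± 2.48 (1.40, 2.44e-05). The lipid receptor gene Trem2 rose by 1.45 log2 (0.00012). Of 23 neutrophil granule genes 9 rose and 0 fell (16 adjusted over the list alone, median 0.73). The collagenase gene Mmp8 led them and went from 8.78 ± 0.700 to 48.6 ± 3.45 FPKM (log2 change 2.34 ± 0.18, adjusted p = 4.64e-05). The others included the lysozyme gene Lyz2 (280 and 683 FPKM, 1.29, 0.000491), Wfdc21 (1.62, 0.00119), the lactoferrin gene Ltf (2.05, 0.0163) and Chil3 (1.81, 0.0121). Further rises were those of Saa3, an acute-phase protein gene (2.16, 0.00963), Fn1 (fibronectin, 1.87, 9.57e-05), Pirb (an inhibitory receptor of myeloid cells, 1.74, 0.000202) and Ly6k (0.288 and 3.79 FPKM, 1.88, 1.6e-05). The macrophage list was called with the preset and with an estimated correlation (adjusted p = 1.26e-10, and adjusted p = 0.0137 with an estimated correlation). The neutrophil granule list was called with the preset correlation alone (5.52e-09, and adjusted p = 0.597 with an estimated correlation). The calls of Saa3, Ltf and Chil3 ended without HET 2 (adjusted p = 0.0516, 0.0767 and 0.0684), and those of Ltf and Chil3 also without HET 3 (0.0706 and 0.0628). With only these groups in the fit that of Chil3 ended (0.0575).

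Immediate early genes also rose in HET cells in vitro, with 7 of 23 up and 0 down (9 adjusted over the list alone). The median was 0.35 (adjusted p = 0.000644, adjusted p = 0.642 with an estimated correlation, and 0.144 without WT 1 at the preset). Fos rose by 1.68 log2 (adjusted p = 2.44e-05), Fosb by 1.59 (0.000249), Dusp1 by 1.05 (0.00379) and Klf4 by 1.02 (0.00134). Among 25 NF-kappaB genes 5 rose and 0 fell (6 adjusted over the list alone). The NF-kappaB median was 0.17 (adjusted p = 0.00278, adjusted p = 0.642 with an estimated correlation, and 0.0603 without WT 1 at the preset). Among the genes that rose were the monocyte chemokine gene Ccl2 (1.47, 0.00134) and the cytokine signalling inhibitor gene Socs3 (1.10, 0.00654). The hypoxia list was called lower (median -0.30, 2 down and 1 up, 4 down and 1 up adjusted over the list alone, adjusted p = 6.63e-05, and adjusted p = 0.687 with an estimated correlation). Higd1a changed by -0.40 (0.0209, and 0.0801 and 0.09 without HET 1 and HET 3). The ribosomal protein list (38 genes, median -0.21, 0 past the threshold by limma and 12 lower adjusted over the list alone) was called lower (adjusted p = 4.2e-11, and adjusted p = 0.642 with an estimated correlation). It was not called after quantile normalization (0.398). The histone genes H2bc8 (-1.11, 0.00012) and H2ac6 (-0.86, 0.0203) fell. So did Trib3 (-0.82, 0.0292), Apln (-0.84, 0.0322), Pim2 (-0.79, 0.0162), Tmem254 (-0.80, 0.0103), Tspan33 (-0.77, 0.00543) and the X inactivation RNA gene Xist (-1.38, 0.00825). Of these H2bc8, Tspan33 and Xist were past the threshold whichever library was left out. The highest adjusted p without a library was 0.0887 for H2ac6 (HET 2), 0.0935 for Trib3 (WT 3), 0.0796 for Apln (HET 1), 0.0582 for Pim2 (WT 3) and 0.0631 for Tmem254 (HET 3). With no filter on low values the calls of H2ac6, Apln, Trib3 and Pim2 ended (0.0601, 0.0897, 0.0881 and 0.0578), and that of Apln also after rescaling to TPM (0.0524) and with only these groups in the fit (0.0517).

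**Figure D2:**
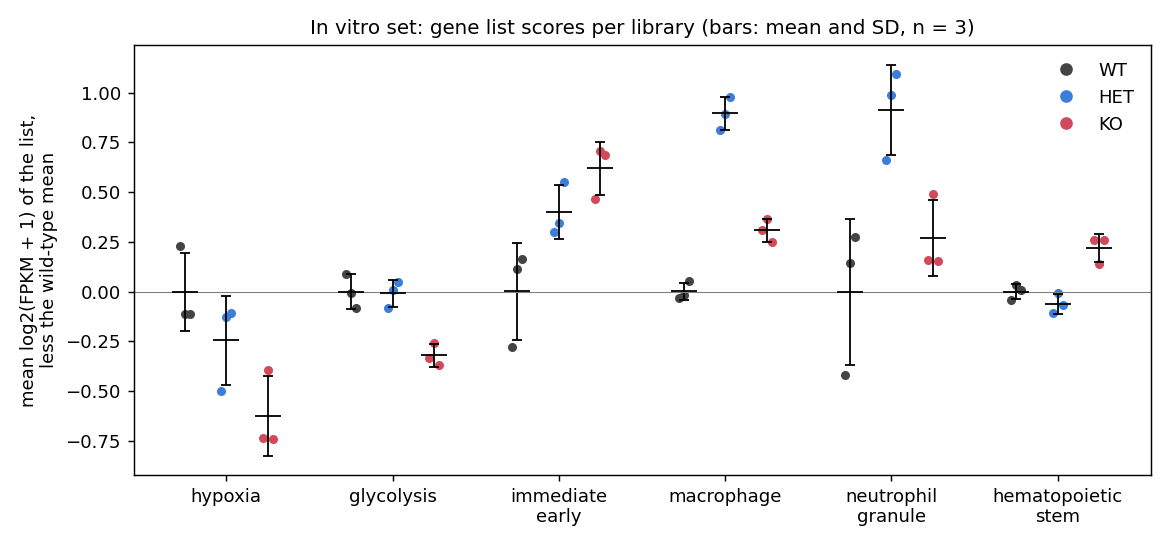
Scores of 6 gene lists in each in vitro library (points), as the mean log2(FPKM + 1) of the list less its WT mean on the y axis, with the mean and SD of the 3 libraries per genotype (bars). The hypoxia and glycolysis scores were lowest in KO, the macrophage and neutrophil granule scores highest in HET, and the immediate early score higher in HET and in KO than in WT.

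By limma, 400 of 10877 genes changed between HET and WT cells in vitro, 320 up and 80 down (80.0% up), with 60 up and 5 down by at least 2-fold and 2547 at unadjusted p under 0.05. The groups did not overlap for 29.1% of genes, against 10% by chance. The split was 262 up and 173 down (60.2% up) after quantile normalization. The lists of hematopoietic stem cells (0 changed, 2 lower adjusted over the list alone, adjusted p = 0.141) and leukemia stem cells (0 changed, adjusted p = 0.508) were not called. Neither were those of fatty acid oxidation (1 lower, adjusted p = 0.141) and PPARG targets (0 changed, adjusted p = 0.811). The fatty acid oxidation gene that fell was Hadh, which encodes a dehydrogenase of the pathway (46.8 and 36.4 FPKM, log2 change -0.35, adjusted p = 0.0462). Its call ended without any library except KO 2 (adjusted p up to 0.15 without HET 3), with no filter on low values (0.0901), with only these groups in the fit (0.0624) and after rescaling to TPM (0.0954). Camera called 11 of 39 lists, 1 of them with an estimated correlation (adjusted p from 0.0137 to 0.736). Of the 10 possible splits of these 6 libraries, 7 gave at least 11 called lists, the real split among them. The number of called lists therefore does not set HET apart from WT. Fry called 4, and the 28 lists that camera did not call had adjusted p from 0.124 to 0.984. The count of genes was 626 without WT 1, 185 without WT 2, 236 without WT 3, 150 without HET 1, 89 without HET 2, 84 without HET 3, 628 without KO 2 and 253 without KO 3. It was 250 with no filter on low values and 4622 with array weights, whose estimation did not converge.

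Compared directly, KO cells in vitro had fewer macrophage, neutrophil granule, glycolysis and hypoxia transcripts than HET cells and more of some stem cell transcripts. Of 12 macrophage markers 5 fell and 0 rose (6 adjusted over the list alone, median -0.32), including Ctss (log2 change -1.90, adjusted p = 0.000205), Trem2 (-1.38, 0.000205) and the macrophage growth factor receptor gene Csf1r (-1.27, 0.000727). This list was called with both correlations (adjusted p = 1.02e-07, and adjusted p = 0.0365 with an estimated correlation). Of 23 neutrophil granule genes 5 fell (8 adjusted over the list alone, median -0.59, adjusted p = 1.85e-07, and adjusted p = 0.477 with an estimated correlation). The largest falls were those of Saa3 (142 to 20.1 FPKM, -2.88, 0.00181), Mmp8 (48.6 to 9.31 FPKM, -2.31, 6.22e-05) and the cystatin genes Stfa3, Cstdc4 and Csta2 (-2.29, -2.26 and -2.09, adjusted p = 0.00289, 0.000674 and 0.00051). Of 24 glycolysis genes 8 fell (13 adjusted over the list alone, adjusted p = 1.37e-09, and adjusted p = 0.232 with an estimated correlation), with Slc2a3 at -1.09 (0.00155) and Slc16a3 at -1.03 (0.00181). Of 24 hypoxia genes 3 fell (13 adjusted over the list alone, adjusted p = 7.12e-09, and adjusted p = 0.53 with an estimated correlation). Of 17 hematopoietic stem cell genes 3 rose and 0 fell (5 adjusted over the list alone, median 0.21, adjusted p = 1.88e-05, and adjusted p = 0.127 with an estimated correlation). These were Hlf (1.13, 0.00051), Pdzk1ip1 (10.3 and 19.6 FPKM, 0.89, 0.00313) and the transcription factor gene Mecom (4.97 and 8.92 FPKM, 0.74, 0.0049). The leukemia stem cell list was called higher (27 genes, 3 up, 4 up and 1 down adjusted over the list alone, median 0.06, adjusted p = 0.00167, and adjusted p = 0.53 with an estimated correlation). Pbx3 changed by 0.62 (0.00389). Ly6k (2.21, 2.66e-06), Capn11 (1.41, 2.37e-05), Slc15a2 (1.38, 6.22e-05), Xist (1.16, 0.0216) and Pcp4l1 (1.14, 0.000727) had the largest rises. The call of Xist ended without HET 1, HET 2, KO 1 or KO 3 (up to 0.113) and with no filter on low values (0.0658). Hlf, Capn11 and Slc15a2 were not tested with a KO library left out, since they then failed the filter.

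By limma, 216 genes changed between KO and HET cells in vitro, 65 up and 151 down (30.1% up), with 9 up and 40 down by at least 2-fold and 1437 at unadjusted p under 0.05. The groups did not overlap for 22.4% of genes, against 10% by chance. Camera called 16 of 39 lists, 5 higher and 11 lower, and 1 with an estimated correlation (adjusted p from 0.0365 to 0.649). The Fabp family list among the 16 held 1 tested gene, Fabp5. Splits of these libraries that mixed the genotypes gave up to 17 called lists, so this number does not set KO apart from HET. Fry called 8, and the 23 lists that camera did not call had adjusted p from 0.119 to 0.824. Among the called lists, the ribosomal protein list was higher in KO (median 0.18, 1 of 38 up and 9 adjusted over the list alone, adjusted p = 1.68e-11, and adjusted p = 0.53 with an estimated correlation). The fatty acid synthesis list was lower (median -0.22, 3 of 18 down and 6 adjusted over the list alone, adjusted p = 1.15e-05, and adjusted p = 0.232 with an estimated correlation). The lipogenic regulator gene Srebf1 changed by -0.43 (0.00823, and 0.0556 and 0.0608 without HET 3 and KO 3). The count of genes was 344 without WT 1, 87 without HET 2, 73 without HET 3, 116 without KO 1 and 103 without KO 3. It was 136 with the filter at FPKM of 5 and 1901 with array weights, whose estimation did not converge.

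HET and KO cells in vitro shared 57 rises and 28 falls against WT, where independent lists would share 4.35 and 1.30. In contrast, 2 genes (Pcp4l1 and Xlr3b) changed in opposite directions. Both comparisons use the same WT libraries, and with unchanged groups against those libraries the simulated number of shared calls was 0.04 on average and at most 2 in 100 runs. That simulation changed no genes and let each gene vary independently, so hardly any calls could arise. It therefore gives no bound for 2 groups with unrelated changes. The log2 changes correlated across genes at r = 0.598 against 0.5 simulated, with a covariance of 0.0325 against 0.0075, a difference of 0.025. Part of the excess may stem from the shared WT libraries, since 3 cannot be split into groups of 2. The HET mean lay between the WT and KO means for 26 of the 57 rises and 21 of the 28 falls. Capn11, Fos, Ly6k and Nr4a1 also rose from HET to KO, which made 4 of the 57, and 0 of the 28 fell further by limma. Of all 320 rises in HET against WT, 87 fell from HET to KO by limma. The calls of Fos and Nr4a1 in KO against HET ended without HET 1, HET 2 or KO 3 (up to 0.187 for Fos without HET 2 and 0.0879 for Nr4a1 without KO 3). That of Fos also ended without KO 2 (0.116), with no filter on low values (0.106), after quantile normalization (0.0644), with median-ratio size factors (0.0602) and after rescaling to TPM (0.0584). The number of shared changes was 154 without WT 1, 32 without WT 2, 56 without WT 3, 44 without HET 1, 25 without HET 2, 158 without KO 2, and 23 without HET 3, KO 1 or KO 3.

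In sorted bone marrow no gene passed the threshold between KO and WT, and the group changes were seen in gene lists. The neutrophil granule list was higher in KO (22 genes, median log2 change 1.33, 0 past the threshold and 1 up adjusted over the list alone, adjusted p = 2.86e-07, and adjusted p = 0.558 with an estimated correlation). In FPKM the antimicrobial granule gene Ngp was at 2094 ± 1943 in WT and 19500 ± 3545 in KO (SD, n = 3, adjusted p = 0.845). The lectin gene Fcnb was at 194 ± 165 and 1039 ± 218 (0.653), and Ltf at 0.0347 ± 0.0353 and 148 ± 42.0 (0.317). The alarmin gene S100a8 of neutrophils took 5.16, 4.52 and 0.143% of summed FPKM in WT, 13.6 and 13.1% in HET and 19.0, 12.6 and 13.9% in KO. Mitochondrially encoded transcripts were lower in KO (13 genes, median -1.29, 0 past the threshold and 7 down adjusted over the list alone, adjusted p = 9.78e-05, and adjusted p = 0.666 with an estimated correlation). The cytochrome b gene CYTB was at 7803 ± 1325 and 3226 ± 792 FPKM (adjusted p = 0.259). Their share of summed FPKM was 2.75 to 3.60% in WT, 2.76 to 2.86% in HET and 0.993 to 1.65% in KO. Immediate early genes were called higher (21 genes, median 0.54, 2 up adjusted over the list alone, adjusted p = 0.0216, and adjusted p = 0.558 with an estimated correlation). Fos was at 1052 ± 256 and 3595 ± 604 FPKM (adjusted p = 0.317). Ribosomal protein genes (38, median -0.75, adjusted p = 0.000818, and adjusted p = 0.666 with an estimated correlation) and cholesterol synthesis genes (9, median -1.63, 1 down adjusted over the list alone, adjusted p = 0.00894, and adjusted p = 0.558 with an estimated correlation) were called lower. Mitotic genes (26, median 0.81, adjusted p = 0.015, and adjusted p = 0.558 with an estimated correlation) were called higher. None of the 6 calls held with an estimated correlation, and fry called 0 lists.

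The lists of the study question were not called between KO and WT bone marrow. Adjusted p was 0.899 for 27 leukemia stem cell genes, 0.726 for 8 hematopoietic stem cell genes, 0.726 for 20 fatty acid oxidation genes and 0.707 for 9 PPARG targets, and 0 of their members passed the threshold by limma. For fatty acid oxidation the median was -0.42, the mean 0.02 and the direction of camera up. The 33 lists not called had adjusted p from 0.123 to 0.899. Limma called 0 of 7246 genes, with 370 (5.11%) at unadjusted p under 0.05, a smallest adjusted p of 0.259 and non-overlapping groups for 12.3% of genes against 10% by chance. Without WT 3 it called 4 genes, all higher in KO, and after quantile normalization 2, both lower. The median log2 change of all genes was -0.19, and -0.03 after quantile normalization, -0.03 with median-ratio size factors and -0.34 after rescaling to TPM. Simulated changes of 4 log2 were recovered for 8.4% of genes in this design, so that differences of this size were mostly not detectable. A simulated list lowered by 0.5 log2 was found in 1 of 5 runs here and in 5 of 5 in vitro, so the lists not called leave shifts open as well. Genes varied independently in these runs, so they do not test list calls where genes are correlated. The immediate early list was not called without WT 2, WT 3 or KO 2 (adjusted p = 0.114, 0.0758 and 0.0938), after rescaling to TPM (0.07) or with a pseudocount of 0.1 (0.0668). The cholesterol list was not called without WT 2, WT 3 or KO 3 (0.164, 0.0565 and 0.0811), nor the mitotic list without WT 2, KO 2 or KO 3 (0.0968, 0.0938 and 0.083) or with a pseudocount of 0.1 (0.0581).

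**Figure D3:**
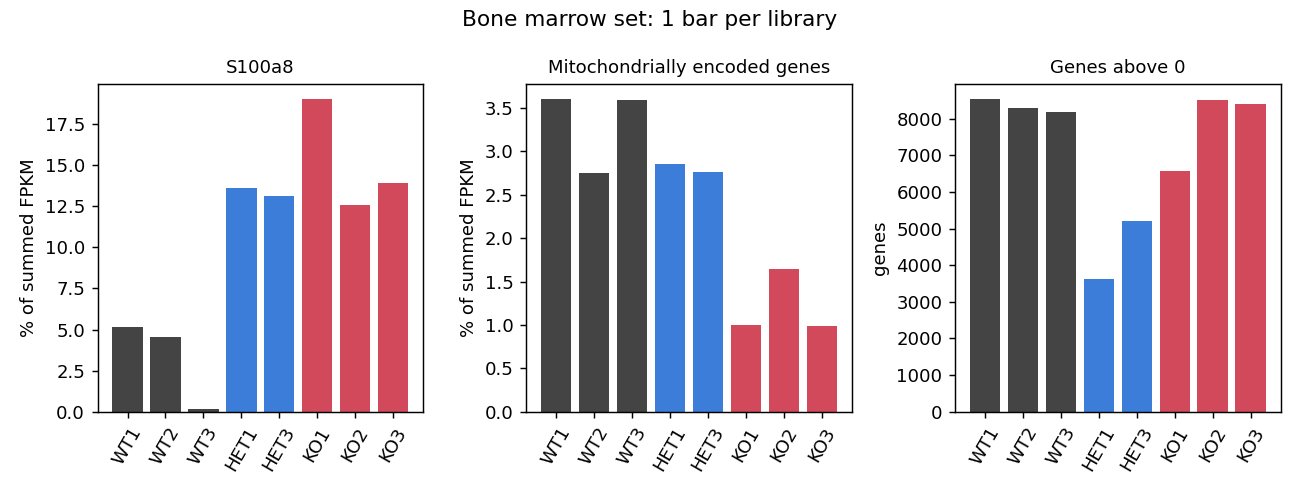
Share of summed FPKM taken by S100a8 (left, %), share taken by mitochondrially encoded genes (middle, %) and number of genes listed above 0 (right), with a bar per bone marrow library for WT, HET and KO. S100a8 took 0.143 to 5.16% in WT and 12.6 to 19.0% in KO, and the HET libraries had 3633 and 5209 genes above 0.

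Between HET and WT bone marrow, 19 genes fell and 0 rose by limma (902 at unadjusted p under 0.05), and 13 of the 19 were listed at 0 in both HET libraries. Those with the largest falls were Phpt1 (WT mean 255 FPKM), Polr2g, an RNA polymerase II subunit gene (184), Chrac1 (208) and the endosomal sorting nexin gene Snx3 (201). They were followed by BC064078 (167), the translocon-associated protein gene Ssr2 (157) and Gemin7 (169.8). All these were at 0 in both HET libraries. The ribosome assembly factor gene Fcf1 was at 459.5 FPKM in WT and at 0 and 0.72 in HET (adjusted p = 0.0118). The median log2 change of all genes was -0.99, so the whole comparison was shifted. The HET libraries were the shallowest. After quantile normalization the median was -0.03 and 12 genes were lower, but the shift stayed with median-ratio size factors (-0.95, 18 genes lower) and after rescaling to TPM (-1.25, 23 lower). The neutrophil granule list was called higher (22 genes, median 0.38, 0 past the threshold, adjusted p = 0.0364, adjusted p = 0.997 with an estimated correlation, and 0.693 after quantile normalization), with Fcnb at 194 and 759 FPKM. The other 38 lists had adjusted p from 0.0789 to 0.997, and fry called 8. The count of genes was 0 without WT 1, WT 2, WT 3, KO 2 or KO 3, 1 without KO 1, 111 without HET 1 and 323 without HET 3, where the remaining HET library was assumed to vary like the others. It was 35 with a pseudocount of 0.1, 0 with only these groups in the fit, 9 with array weights and 0 when only the 1857 genes above 0 in every library were fitted, which leaves out called genes at 0 in HET by construction. The neutrophil granule list was not called without WT 2, WT 3 or HET 1 (0.0613, 0.34 and close to 1).

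Between KO and HET bone marrow, 12 genes rose and 0 fell by limma (817 at unadjusted p under 0.05). The largest rises were those of Polr2g, Chrac1, Snx3, Gemin7 and the lysosomal protease gene Ctsd, which were listed at 0 in both HET libraries and at means of 179.5, 165, 161, 205 and 189 FPKM in KO. Mitochondrially encoded genes were called lower (median -1.06, 0 past the threshold and 7 down adjusted over the list alone, adjusted p = 0.000473, adjusted p = 0.957 with an estimated correlation, and 0.0915 without HET 1). The other 38 lists had adjusted p from 0.431 to 0.938, and fry called 4. The median log2 change of all genes was 0.83, and 0.01 after quantile normalization, 0.92 with median-ratio size factors and 0.93 after rescaling to TPM. The count of genes was 0 without any of the WT or KO libraries, 119 without HET 1 and 330 without HET 3, where the only HET library left was assumed to vary like those of the other groups. It was 31 with a pseudocount of 0.1 and 0 with only these groups in the fit, with array weights or with genes above 0 in every library.

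The in vitro and bone marrow sets shared 0 genes called between KO and WT, since limma called 0 in bone marrow at this threshold. Of 199 in vitro calls measured in bone marrow, 106 (53.3%) had the same sign there, and the changes correlated at r = 0.00690 across genes, which are not independent replicates. A test of the difference itself called 63 of 10041 genes, 41 with a positive and 22 with a negative difference of the in vitro less the bone marrow log2 change (807 at unadjusted p under 0.05). The 10 named genes of this test, such as Trip6, Psma8, Ltf and Mettl23, had in vitro changes between -0.26 and 0.40 log2. In bone marrow Trip6 was at 45.0 FPKM in WT and 0.272 in KO, and Mettl23 at 0.0106 and 48.4. In fits of each set alone the test called 53 genes with a normal approximation and 0 with a t distribution.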

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

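The fits of each set alone with a t distribution were chosen only after the result was seen. The fits with a normal approximation were planned, and the t distribution was added after their count was known, because a normal approximation is not suited to so few libraries.

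The KO against WT change differed between the in vitro and bone marrow sets for 63 of 10041 genes in the joint limma fit, which tests the difference itself. The in vitro minus bone marrow difference in log2 change was 5.28 for Trip6, a focal adhesion LIM protein gene, 4.98 for the testis proteasome subunit gene Psma8, 4.66 for Tlcd2, 4.63 for the nuclear export receptor gene Xpo6 and 4.61 for the tryptophanyl-tRNA synthetase gene Wars1. It was -6.89 for Ltf, -5.71 for the methyltransferase gene Mettl23, -5.32 for the histamine-degrading enzyme gene Hnmt, -5.26 for the kinetochore gene Ska2 and -5.15 for the cilium gene Tmem216. The differences came from bone marrow, where group means moved to or from values near 0. Mean FPKM in WT and KO bone marrow were 45.0 and 0.272 for Trip6, 31.6 and 0 for Psma8, 23.1 and 0 for Tlcd2, 21.2 and 0 for Xpo6, and 34.2 and 0.311 for Wars1. They were 0.0347 and 148 for Ltf, 0.0106 and 48.45 for Mettl23, 0 and 44.4 for Hnmt, 1.51 and 60.9 for Ska2, and 0.430 and 47.5 for Tmem216. The in vitro changes of these 10 genes lay between -0.26 and 0.40.

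Chance was not excluded for this count, because 43 of 100 splits of the libraries gave at least 63 calls, with 120 as the highest of the other splits. Fitting each set alone with its own spread gave adjusted p of 8.64e-06 to 0.00685 for the 10 named genes with a normal approximation and 0.51 to 0.635 with a t distribution, where 0 of 10 passed the threshold. In simulated data the joint fit made 34.2 false calls per run on average, the separate fits 45.0 with a normal approximation and 0.6 with a t distribution. The call of Ska2 ended without bone marrow KO 3.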

How the results depend on the processing

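Leaving out genes of chromosomes X and Y, keeping genes above 0 in every bone marrow library, the alternatives for changes shared by HET and KO, and separate fits with a t distribution were chosen only after the result was seen. The list of mast cells, basophils and eosinophils in KO against WT in vitro reversed the sign of its median of -0.13, which ranged from -0.51 without WT 1 to 0.14 without WT 3, where it was not called (adjusted p = 0.483). No other called result reversed its direction. Of the alternative values, 183 counts or main values stayed and 103 moved, and 568 list results kept their call and 112 others lost it. A count stayed if it was within 1.5 times the reported count, and the Fabp4 difference if it moved by less than the SD of the WT libraries. Counts of 0 that remained at 0 are among those that stayed. Of the others, 5096 named-gene results kept their side of the threshold, 445 lost and 214 gained a call. For changed genes in vitro, the filter and the groups in the fit mattered. With no filter on low values the counts were 152 (KO against WT) and 250 (HET against WT), with 30 shared changes. With the filter at FPKM of 5 KO against HET gave 136. With only the 2 groups in the fit KO against WT gave 176 and shared changes 33, while KO against HET gave 323. Array weights, whose estimation did not converge, gave 5340, 4622 and 1901 genes, 2917 shared changes and 5 differences between the sets. In bone marrow, HET against WT gave 35 with a pseudocount of 0.1, 12 after quantile normalization, 9 with array weights and 0 with 2 groups in the fit or genes above 0 in every library. KO against HET gave 31 with a pseudocount of 0.1, 6 with no filter, 7 after quantile normalization and 0 with 2 groups in the fit, array weights or genes above 0 in every library. KO against WT gave 2 and shared HET and KO changes 1 after quantile normalization, which also gave 3 called lists for HET against WT. The difference between the sets gave 34 after quantile normalization, 53 in separate fits with a normal approximation and 0 with a t distribution. With an estimated correlation camera called 0, 1 and 1 lists in vitro and 0, 0 and 0 in bone marrow, which the preset correlation of 0.01 by construction does not allow for. The cause was not tested for the other values that moved or reversed.

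With the replicate number as a replicate block, KO against WT in vitro gave 172 genes, HET against WT 234, shared changes 36 and the difference between the sets 40. In bone marrow the replicate block gave 0 genes for HET against WT and for KO against HET, and 2 called lists for HET against WT, and it moved no other count by over 1.5 times. It also ended the calls of the lists erythroid (HET against WT, adjusted p = 0.0556) and stress response (KO against HET, 0.0597) in vitro and immediate early (KO against WT, 0.0536) in bone marrow. Libraries with the same number deviated together at correlations of -0.303 to 0.181 in vitro and -0.0191 to 0.0323 in bone marrow, and 2 of 9 and 3 of 8 libraries correlated best with their own number. No pairing by number was seen, but so few libraries per genotype cannot exclude it. This check was made after the block counts had been seen.

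Leaving out each library in turn gave 66 to 475 genes for KO against WT in vitro, 84 to 628 for HET against WT and 73 to 344 for KO against HET, and 13 to 20, 10 to 12 and 14 to 20 lists. Shared HET and KO changes ranged from 23 to 158. In bone marrow the counts were 0 to 4, 0 to 323 and 0 to 330 genes and 3 to 8, 0 to 2 and 0 to 1 lists. KO against WT called 3 lists without WT 2, HET against WT 0 without WT 2, WT 3 or HET 1 and 2 without WT 1, and KO against HET 0 without HET 1. The difference between the sets gave 36 to 216 genes, with 40, 37 and 40 without in vitro WT 1 to 3 and 37, 39 and 36 without in vitro KO 1 to 3. It gave 194, 189 and 205 without bone marrow WT 1 to 3, 136 and 135 without HET 1 and 3, and 216, 200 and 195 without KO 1 to 3. The Fabp4 difference ranged from -0.181 to -0.0163 FPKM. Depth limits the HET bone marrow libraries most, at 3.96 and 11.6 M fragments.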

Other observations

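The tests of a single library behind the hypoxia genes, of mature neutrophil transcripts, of the third WT bone marrow library, of called genes above 0 in every library, of pairs of HET and KO libraries, of sex chromosome genes and of the neighbours of Fabp4 were chosen only after the result was seen.

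Further gene groups were called by camera between KO and WT cells in vitro. Genes of mast cells, basophils and eosinophils were lower (19 genes, 1 down, 6 down and 1 up adjusted over the list alone, median -0.13, adjusted p = 0.015, and adjusted p = 0.614 with an estimated correlation). Ear2 passed the threshold, and the major basic protein gene Prg2 was at 2069 ± 281 FPKM in WT and 1117 ± 193 in KO (adjusted p = 0.0516) and the eosinophil peroxidase gene Epx at 404 ± 53.2 and 216 ± 19.8 (0.0512). This list was not called without WT 2, WT 3 or KO 2 (0.0872, 0.483 and 0.116) or after quantile normalization (0.0933). Its median was -0.51 without WT 1, -0.03 without WT 2, 0.14 without WT 3 and 0.00 without KO 2, so that its direction hung on single libraries. MYC targets were higher (30 genes, 3 up and 1 down, 8 up and 2 down adjusted over the list alone, median 0.16, adjusted p = 0.0313, adjusted p = 0.625 with an estimated correlation, and 0.226 without WT 1). The members that rose, Gnl3 (0.72), Nop2 (0.72) and Polr1b (0.63), serve ribosome production, while Ldha fell. Their calls ended without WT 2, WT 3, KO 1 or KO 3 (adjusted p up to 0.116 for Gnl3, 0.163 for Nop2 and 0.193 for Polr1b). They also ended without HET 2 for Nop2 (0.0515) and Polr1b (0.0675) and without WT 1 for Polr1b (0.0645). With no filter on low values all 3 ended (0.0763, 0.103 and 0.103), after rescaling to TPM those of Nop2 and Polr1b (0.0604 and 0.0645) and after quantile normalization that of Polr1b (0.0617). Neutrophil granule genes were higher (23 genes, 2 up, 5 adjusted over the list alone, median 0.24, adjusted p = 0.0396, and adjusted p = 0.625 with an estimated correlation), but not without WT 1 (0.85) or KO 2 (0.874) or with a pseudocount of 0.1 (0.0557). Interferon genes (22, median 0.19, 0 changed by limma and 3 up adjusted over the list alone, adjusted p = 0.00913, and adjusted p = 0.568 with an estimated correlation) were called higher. So were dendritic cell genes (8, median 0.16, 1 up, 1 adjusted over the list alone, 0.0351, and adjusted p = 0.581 with an estimated correlation). The interferon list was not called without WT 1, WT 2 or KO 2 (0.0954, 0.0808 and 0.0899), nor the dendritic list without these libraries (0.126, 0.0872 and 0.218) or with median-ratio size factors (0.052). Genes of oxidative phosphorylation (39, median -0.11, 0 changed, 0 adjusted over the list alone, 2.97e-05, and adjusted p = 0.587 with an estimated correlation) were called lower. So were those of DNA replication (33, median -0.11, 1 down, 1 adjusted over the list alone, 0.000435, and adjusted p = 0.581 with an estimated correlation) and the genes around Fabp4 (13, median -0.17, 1 down, 2 adjusted over the list alone, 0.00806, and adjusted p = 0.233 with an estimated correlation).

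In the other in vitro comparisons, the directions given are those of lists called by camera at the preset correlation. None of these lists was called with an estimated correlation. HET cells had lower oxidative phosphorylation genes than WT by that call (39, median -0.13, 0 changed, 0 adjusted over the list alone, adjusted p = 2.44e-07, adjusted p = 0.643 with an estimated correlation, and fry adjusted p = 0.208). They had lower erythroid genes (18, median -0.11, 1 down, the alpha globin gene Hba-a1, 1 adjusted over the list alone, 0.046, and adjusted p = 0.736 with an estimated correlation). The call of Hba-a1 ended without HET 1 (0.0519) or HET 3 (0.0631). The erythroid list was not called without WT 2 (0.28) or HET 3 (0.228), after quantile normalization (0.147) or with median-ratio size factors (0.0597). HET cells also had lower genes around Fabp4 (0 changed, 0 adjusted over the list alone, median -0.14, 0.0141, and adjusted p = 0.422 with an estimated correlation). They had higher MYC targets (1 up, 8 up and 1 down adjusted over the list alone, median 0.25, 0.00204, adjusted p = 0.736 with an estimated correlation, and 0.0603 and 0.131 without WT 1 and HET 1). KO cells had higher dendritic cell genes than HET cells (8, 1 up, 6 adjusted over the list alone, median 0.26, adjusted p = 5.46e-05, and adjusted p = 0.349 with an estimated correlation). They had higher immediate early genes (23, 2 up, 4 up and 1 down adjusted over the list alone, median 0.19, 0.00082, and adjusted p = 0.53 with an estimated correlation). They also had lower mast cell, basophil and eosinophil genes (0 changed, 3 down adjusted over the list alone, median -0.30, 0.00247, and adjusted p = 0.566 with an estimated correlation). DNA replication genes were lower (median -0.10, 0 changed, 0.00753, adjusted p = 0.649 with an estimated correlation, and 0.517 and 0.0619 without HET 1 and KO 3), as were cholesterol synthesis genes (median -0.10, 1 down, 0.0167, adjusted p = 0.566 with an estimated correlation, and 0.42 and 0.0519 without HET 1 and KO 3). Stress response genes were also lower (median -0.09, 0 changed, 0.0471, adjusted p = 0.53 with an estimated correlation, and 0.0554 with median-ratio size factors). Their call ended in 7 of 9 cases with a library left out (0.112, 0.0626, 0.0658, 0.133, 0.0625, 0.128 and 0.113 without WT 1, WT 2, WT 3, HET 1, HET 2, KO 1 and KO 3). Sex-linked genes differed between the genotypes in vitro, with the Y gene Ddx3y at 3.19 FPKM in WT, 9.93 in HET and 6.46 in KO and Xist at 42.0, 15.4 and 36.1. Every in vitro library held both, at 2.39 to 11.7 FPKM for Ddx3y and 12.3 to 49.65 for Xist, so libraries may mix cells of both sexes. The sex-linked list was called in all 3 comparisons (adjusted p = 0.00275, 0.000708 and 0.00753, and adjusted p = 0.343, 0.597 and 0.504 with an estimated correlation). Genes of X and Y made up 19 of 400 calls of HET against WT (4.75%) and 2.98% of tested genes (Fisher's exact p = 0.0489), and without them 375 genes changed. Leaving them out does not test an effect of sex on other genes. For the macrophage and neutrophil granule genes in HET cells, donor sex, culture and handling cannot be told apart from genotype. In bone marrow Xist was at 46.9, 48.3 and 9.54 FPKM in WT, HET and KO, and the Y gene Eif2s3y was at 0 in WT and HET and at 3.90 in KO. Ddx3y did not split by genotype there, at 0, 0 and 3.90 FPKM in the WT libraries, 0 in both HET and 0, 4.72 and 3.14 in KO.

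Lower hypoxia and glycolysis genes in KO cells in vitro are a pattern that may reflect the genotype, as a hypothesis. The hypoxia median less the all-gene median stayed between -0.717 and -0.737 under every scaling tried. Median-ratio and TPM scaling divide a library by a single factor, which nearly cancels in this difference, so they could not test it. Scaling is argued against only as far as quantile normalization tests it, which could have moved the value and did not. A single library is argued against, because the median stayed between -0.494 and -0.782 whichever library was left out. Culture or handling that differed between the genotypes cannot be told apart from genotype, since the labels give no batch. The sex of the donors, which the labels do not give, cannot be told apart from genotype for the hypoxia genes, since the Y genes differed between the genotypes. The hypoxia scores of HET and KO libraries overlapped. For the glycolysis genes donor sex alone is argued against, because Ddx3y and Xist moved most in HET and this score did not. The glycolysis score was 6.79 ± 0.09 in WT, 6.78 ± 0.07 in HET and 6.47 ± 0.06 in KO (mean log2(FPKM + 1), SD, n = 3). Within genotypes the hypoxia and immediate early scores of the 9 libraries had r = -0.114 (permutation p = 0.806, 216 permutations) and Spearman's rho = -0.05 (permutation p = 0.898). Without the 2 libraries farthest from the median r was 0.279, which decides nothing.

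Higher neutrophil granule genes in KO bone marrow may come from the marrow composition or from the sorted cells themselves. The list median less the all-gene median was 1.36 to 1.56 under the scalings tried. Here too scaling is argued against only as far as quantile normalization tests it, since a single factor per library nearly cancels. The third WT library alone, where S100a8 was lowest, is argued against (median 1.76 and camera adjusted p = 1.03e-05 without it). Mature neutrophils among the sorted cells stay open. The 13 abundant genes of a list named immature granule genes, which also holds S100a8 and S100a9, had a median log2 change of 3.77. That of the 8 abundant mature genes was -0.08, a difference of 3.85 (permutation across genes, which are not independent, p = 0.00477, 100000 resamples). This decides nothing, because abundant meant a mean of at least 50 FPKM over WT and KO together. Ltf (0.0347 and 148 FPKM in WT and KO) and Cd177 (29.8 and 254) passed through KO. Mature genes that moved either way, such as Fpr1 and Il1r2, fell below it. All 8 mature genes were also at 50 FPKM or more in WT, so that their high baseline can hide a small share. Of 23 mature markers, 14 had a lower and 9 a higher mean in KO. Mean FPKM in WT and KO were 22.9 and 13.6 for Retnlg, 2.99 and 1.04 for Cxcr2, 87.2 and 9.26 for Il1r2 and 22.8 and 5.42 for Clec4d, but 2.83 and 29.7 for Mmp9, 19.5 and 49.7 for Trem1, 0.00975 and 53.4 for Fpr1, with 1 KO library above 0, and 59.7 and 519 for Stfa2l1. For the immature markers they were 3681 and 26630 (Camp) and 2094 and 19500 (Ngp). Donor sex stays open too, since Xist was at 5.01 to 13.8 FPKM in the KO and 37.6 to 57.2 in the WT libraries. Earlier granulocyte stages, and a true difference between the genotypes, were not tested further.

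Genes lower in HET bone marrow could be losses of transcripts in the HET libraries, which were the shallowest. Low depth alone is argued against for the 13 called genes listed at 0 in both HET libraries. These had at least 60.69 FPKM in every WT library. At the HET depths of 3.96 and 11.6 M fragments, such levels would be worth many fragments per kilobase of transcript. Loss of transcripts before sequencing and failed estimates at 0 were not tested. Of 3770 genes above 0 in every WT and KO library, 557 were at 0 in both HET libraries where independent loss gave 462 (ratio 1.21), which was set beforehand as evidence against random loss. That bound decides nothing, because in 5075 genes above 0 in every WT library the zeros of a HET and a KO library exceeded independence by 1.18 to 1.43 times and those of the HET pair by 1.17 times. Why zeros coincide between libraries was not tested. Among the 19 called genes 1, Slpi, was above 0 in every library with both HET values over 2-fold below every WT value (632 and 631 FPKM against 2255, 2780 and 3884). This is too few to decide. Random loss, other than by low depth alone for those 13 genes, and genotype cannot be told apart here.

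Fabp5 fell in KO in vitro while the 5 other tested genes within 1 Mb of Fabp4 had a median log2 change of 0.03 (0.0294, median absolute deviation 0.117) and ran from -0.317 (Zbtb10) to 0.318 (C030034L19Rik). The wider list of 13 genes around Fabp4, which includes Fabp5, was called lower in KO (median -0.17) and in HET (-0.14), as given above. For the gene counts of 3 against 3 libraries the 10 possible splits are too few for a share under 0.05. In vitro KO against WT gave 325 genes and at most 1 in the other splits, so that 1 of 10 splits gave as many. HET against WT gave 400 and at most 0 otherwise (1 of 10), KO against HET 216 and at most 0 (1 of 10), and KO against WT in bone marrow 0 and at most 0 (10 of 10). For called lists the values were 18 and at most 17 (1 of 10), 11 and at most 13 (7 of 10), 16 and at most 17 (2 of 10), and 6 and at most 1 in bone marrow (1 of 10). In vitro the number of lists called at the preset correlation therefore does not set the genotypes apart from mixed groups.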
